A study of Mus musculus with 8 samples.

How the data were processed

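Messenger RNA was measured by 10x droplet sequencing in 8 libraries of adult mouse testis cells. Per the labels, testes of at least 2 mice were digested with collagenase and trypsin for each sort, spermatogonia were enriched on Percoll and sorted as CD9-bright cells that were ID4-EGFP-bright, ID4-EGFP-dim or not selected on EGFP, spermatocytes and spermatids were separated by sedimentation at unit gravity, and 3 replicate preparations of unselected spermatogenic cells were called steady-state. Nothing in the labels says more about whether the 3 replicates are separate animals. A p therefore measures how much a difference between classes varied from library to library here, and cannot be read as a spread between animals. The deposited values are raw UMI counts per gene and barcode, integers per the file headers, in 1 filtered matrix per library. Per the submitters' processing notes they were made with Cell Ranger, bcl2fastq and FastQC against builds named mm10 and GRCm38, with versions not given in the sources used here. Sequencing reads were not analysed here, and 3 whole-series aggregates of the same barcodes were not used. The files hold 27998 genes, of which 27722 matched GENCODE M21, with 1084 on the X chromosome, 733 on the Y and 13 mitochondrial. Of 27998, 56 symbols were duplicated and were told apart by gene identifier, and no gene was named for the reporter.

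Barcodes with under 500 detected genes or over 20% mitochondrial UMIs (289) and doublets predicted by scrublet per library (196, 1.12%) were left out of the classes, and 17010 cells were kept. The filter took most from EGFP-bright (189), and predicted doublets ranged from 0.108% there to 2.20% in EGFP-dim. Genes were divided at random (seed 1) into a clustering part of 12986 and a held-out part of 15012, and all fixed lists and all X-linked, Y-linked and mitochondrial genes were held out, except cell type markers, which were put in the clustering part. Counts were scaled to 10000 per cell, log-transformed and reduced from 2000 variable genes to 30 principal components, and cells were clustered with 15 neighbours and the Leiden method at resolution 1.0. Of 29 clusters 25 were named from the fixed markers of 13 cell types, by the score of at least 3 markers detected in at least 10% of cells and by the 10 leading genes, and 4 stayed unnamed. Markers, lists, tests and settings were fixed before the data were examined, while the naming rule was chosen after. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

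UMIs were summed per class and library where the class had at least 20 cells. Held-out genes that are no markers were tested with edgeR quasi-likelihood (TMM, filterByExpr, two-sided) with the library as a block, since the class sums of a library come from 1 preparation. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change, and "rose" and "fell" are used of such genes only. The design called for the 3 steady-state libraries with 20 cells of both classes in each. Replicate 3 has fewer early spermatocyte-like cells, so the first 2 contrasts are given over all libraries with 20 cells of both classes, which the design listed as another choice of libraries, with 5 and 3 of them. In these the other libraries are groups of 1 and stand in as replicates of the class difference. Residual degrees of freedom were 4, 2, 2 and 2, and biological coefficients of variation 0.257, 0.0825, 0.400 and 0.152, in the order of development. Lists were tested with camera at a preset correlation of 0.01 and beside it with an estimated one, adjusted over lists and contrasts. A gene with 0 counts on 1 side is given as a bound against a floor of 3 counts over the group, and genes with 1 to 3 counts as a ratio of sums with a counting interval.

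Fixed lists, with members found, were stem cell (18), progenitor (8), differentiation (9), GDNF and FGF signalling (19), retinoid (20), cell cycle (35), synapsis and recombination (36), piRNA (23), spermatid chromatin (14), acrosome (17), flagellum (29), general glycolysis (16), testis glycolysis (9), nuclear oxidative phosphorylation (43), X genes with autosomal testis copies (13), those copies (12), DNA methylation (8) and immediate early and dissociation stress (20), plus X-linked, Y-linked, mitochondrially encoded and 86 cytosolic ribosomal protein genes. Members that are markers left a list in the tests but not in whole-library comparisons. Tbxt, Six6os1, Iho1, Majin, Terb1, Terb2, Shoc1, H1f7, H1f9, H1f6, Sp56, Dnai1 and Dnmt3c were not found under those symbols.

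Groups of 1 library were compared without a test, over all deposited barcodes, as ratios of counts scaled to the library total (CPM) of genes with at least 100 UMIs over both, and list medians were placed among 10000 random lists matched over 20 expression bins. Within a class, both libraries needed 50 cells. Intervals are exact Poisson or binomial 95% intervals, cover counting error only and say nothing of preparations or animals. At the depth of EGFP-dim, 199 UMIs of Id4 give 6.17 CPM with an interval of 5.34 to 7.09. Detection per cell was read after thinning each cell to 2000 UMIs.

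The rule for named genes, fixed before the data were examined, took from each test the 10 largest rises and 10 largest falls with at least 20 CPM in the higher class and the same direction in all libraries, from each pair the 10 highest and 10 lowest ratios at 20 CPM, up to 4 members of each list, and Id4 in every library. Symbols of the form Gm plus digits or ending in Rik were passed over, and clone names were added to these after the data were seen. Of the genes the rule gives, those with a known role are named first, and not all are printed. Alternatives were DESeq2 size factors, library size alone, no low-count filter, no block, no fold threshold, other cell filters and doublets kept. Others were resolutions 0.5 and 2.0, seed 2 and leaving out each steady-state library. For pairs they were TMM, equal cell totals, filtered cells, 20 UMIs and thinned cells. Further ones were added after seeing the data: spermatocytes of cluster 22 alone, each kind of library alone, leaving out any library in the first 2 contrasts, and named germ cell classes alone. The fits were tested on simulated data with the same sums, spread and 200 changed genes. Recovery asked for an adjusted p under 0.05 and the right direction, without the 2-fold limit. Of the 2-fold changes 37.8%, 60.2%, 1.04% and 80.2% were recovered in the 4 contrasts in the order of development. Of the 4-fold changes 87.6%, 75.6%, 23.2% and 95.7% were. Far more than 200 genes passed in each real contrast, so these shares do not say how often the reported tests find such a change. A gene that did not pass, above all from spermatocytes to round spermatids, may still have changed.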

Results

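Cells of the adult mouse testis were profiled by droplet RNA sequencing in 8 libraries that form 6 groups, with 17491 barcodes in all. Spermatogonia, the mitotic germ cells at the base of the seminiferous tubule, were sorted as cells bright for the surface protein CD9 from mice with an ID4-EGFP reporter. The sort gave 1 EGFP-bright library of 2770 barcodes, 1 EGFP-dim library of 2136 and 1 library of CD9-bright cells not selected on EGFP, of 2039. Spermatocytes, the cells in meiosis, and spermatids, their haploid products, were each enriched by sedimentation at unit gravity into 1 library, of 4233 and 1662 barcodes. Unselected spermatogenic cells, called steady-state here as in the labels, gave 3 replicate libraries of 1305, 1468 and 1878 barcodes. The barcodes equalled the cell numbers in the labels in all 8 libraries. Steady-state was the only replicated group, so only comparisons that rest on several libraries carry a test, and all other values describe single libraries.

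Total UMI counts were 39390769 for EGFP-bright, 32238639 for EGFP-dim, 22825533 for EGFP-unselected, 129223709 for the spermatocyte fraction and 46467639 for the spermatid fraction. The steady-state replicates held 44190861, 46459840 and 46959184 UMIs. Median UMIs per barcode ranged from 8892 in EGFP-unselected to 27240.5 in the spermatid fraction, so shares of cells with a transcript are given after thinning every cell to 2000 UMIs. Mitochondrial transcripts made up a median of 9.08% of UMIs per EGFP-bright barcode, 5.91% in EGFP-dim, 5.70% in EGFP-unselected, 1.30% in the spermatocyte fraction and 0.0686% in the spermatid fraction. In the steady-state replicates this median was 0.232%, 0.227% and 0.281%.

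The first question was which cell types each sort or fraction held. Clusters were named from marker genes, and the names stand for cells like that type. EGFP-bright was made of undifferentiated spermatogonia-like cells, 2113 of 2579 kept cells or 81.9% (exact binomial 95% interval 80.4 to 83.4), while EGFP-dim held 49.3% (47.1 to 51.5) differentiating spermatogonia-like cells and 5.77% (4.81 to 6.87) undifferentiated ones. Among its 2061 kept cells EGFP-dim also held 340 early spermatocyte-like cells, against 13 in EGFP-bright. The larger cluster of peritubular myoid-like cells, cluster 10, had 348 cells of EGFP-dim and 11 of EGFP-bright. EGFP-unselected held 34.8% (32.7 to 37.0) differentiating and 13.0% (11.5 to 14.5) undifferentiated spermatogonia-like cells, with 19.7% peritubular myoid-like and 13.1% endothelial-like cells. The shares describe cells chosen by the EGFP and CD9 gates, not the make-up of the testis. Cluster 8, with 791 EGFP-dim and 534 EGFP-unselected cells, was named differentiating but took the early spermatocyte name under other settings, and the differentiating share then moved to 10.3% in EGFP-dim and 6.53% in EGFP-unselected with predicted doublets kept.

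Mid to late spermatocyte-like cells, those of the pachytene to diplotene steps of meiosis, made up 95.2% (94.5 to 95.9) of the spermatocyte fraction, in which round spermatid-like cells were 2.57%. The spermatid fraction held 41.6% (39.2 to 44.0) round spermatid-like, 15.7% (13.9 to 17.5) condensing spermatid-like and 18.1% (16.3 to 20.1) mid to late spermatocyte-like cells. The labels give a typical purity of 85% for such fractions, counted by morphology under phase contrast, whereas these shares count kept barcodes by transcripts. Over the 3 steady-state libraries the mean share was 37.2% ± 11.9 (SD, n = 3) for condensing spermatid-like cells, 18.2% ± 10.9 for round, 16.3% ± 3.30 for mid to late spermatocytes, 5.87% ± 4.70 for differentiating spermatogonia and 4.04% ± 3.07 for early spermatocytes. Replicate 3 had 0.489% of its cells in each of the last 2 classes, against 8.01% to 9.13% and 5.77% to 5.85% in replicates 1 and 2. Clusters left unnamed held 0.233% of EGFP-bright, 1.31% of EGFP-dim, 6.21% of EGFP-unselected, 1.26% of the spermatocyte fraction, 14.9% of the spermatid fraction and 12.9%, 10.5% and 24.9% of the steady-state replicates. The mid to late share of the spermatocyte fraction was 60.1% with the strict cell filter. The steady-state mean was 28.3% for mid to late spermatocytes with doublets kept, and for early ones 6.88% at resolution 2.0 and 0 at resolution 0.5. Most class shares moved with the clustering settings, so they describe this division of the cells.

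**Figure D1:**
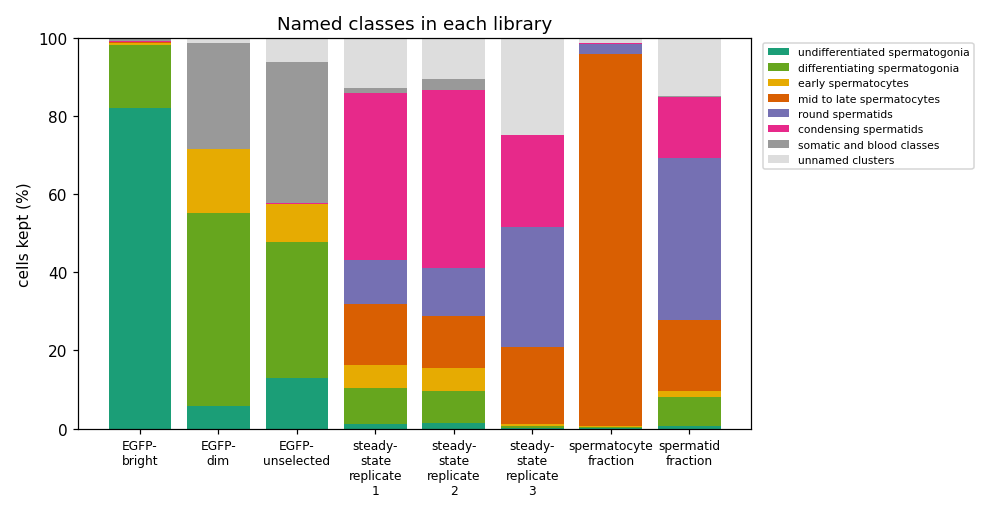
Stacked bars give the percent of kept cells (y axis) in each named class for the 8 libraries (x axis), from 1282 cells in steady-state replicate 1 to 4196 in the spermatocyte fraction. EGFP-bright is mostly undifferentiated spermatogonia-like (81.9%), the spermatocyte fraction mostly mid to late spermatocyte-like (95.2%), and steady-state replicate 3 nearly lacks spermatogonia.

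Id4 (ENSMUSG00000021379; GRCm38 chromosome 13, 48261228 to 48266026, plus strand, 3 exons) encodes an inhibitor of basic helix-loop-helix transcription factors, and its reporter defined the sort. Id4 stood at 102.5 CPM (counts scaled to the library total) in EGFP-bright (Poisson 95% interval 99.4 to 105.7, 4039 UMIs), 6.17 in EGFP-dim (5.34 to 7.09, 199 UMIs) and 21.6 in EGFP-unselected (19.7 to 23.5), in the order of the gates. The spermatocyte fraction reached 89.2 CPM (87.6 to 90.9), the spermatid fraction 36.2 (34.5 to 38.0), and the steady-state replicates 53.9, 46.9 and 28.0. Within classes, mid to late spermatocyte-like cells held 130.3, 117.5 and 52.7 CPM in the steady-state replicates, 91.9 in the spermatocyte fraction and 115.0 in the spermatid fraction. Id4 is also 1 of the markers that named the undifferentiated class, so these class values carry no test. Clusters 14, 26, 27 and 28 held the mid to late class in the spermatocyte fraction, cluster 22 in steady-state replicates 1 and 2, and cluster 16 in replicate 3. Undifferentiated spermatogonia-like cells held 121.5 CPM in EGFP-bright, where clusters 2 and 1 made up the class, and 20.4 (14.5 to 28.0, 39 UMIs) in EGFP-dim, where cluster 1 did. Round spermatid-like cells of the spermatid fraction held 9.38.

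After thinning to 2000 UMIs, 16.8% of EGFP-bright cells (15.4 to 18.3) and 19.0% of mid to late spermatocyte-like cells of the spermatocyte fraction (17.8 to 20.2) had an Id4 UMI, against 57.4% and 89.2% unthinned. The former share is over all EGFP-bright barcodes, and in the undifferentiated class of that library it was 20.1% (18.4 to 21.8). Over all barcodes of EGFP-dim the share was 1.97% (8.01% unthinned), and in differentiating spermatogonia-like cells of that library 0.394%. Somatic cells of EGFP-dim, at a median depth of 6384.5 UMIs against 13208 for the library, showed 5.94% (4.12 to 8.23), a larger share than in differentiating spermatogonia-like cells of the same library. Gfra1, which encodes the receptor for the niche factor GDNF, was detected in 14.0% of EGFP-bright cells but in 12 of 3996 (0.155% to 0.524%) of the same spermatocyte-like cells. Of the 556 somatic cells of EGFP-dim 3 had a Gfra1 UMI before thinning and 0 after.

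**Figure D2:**
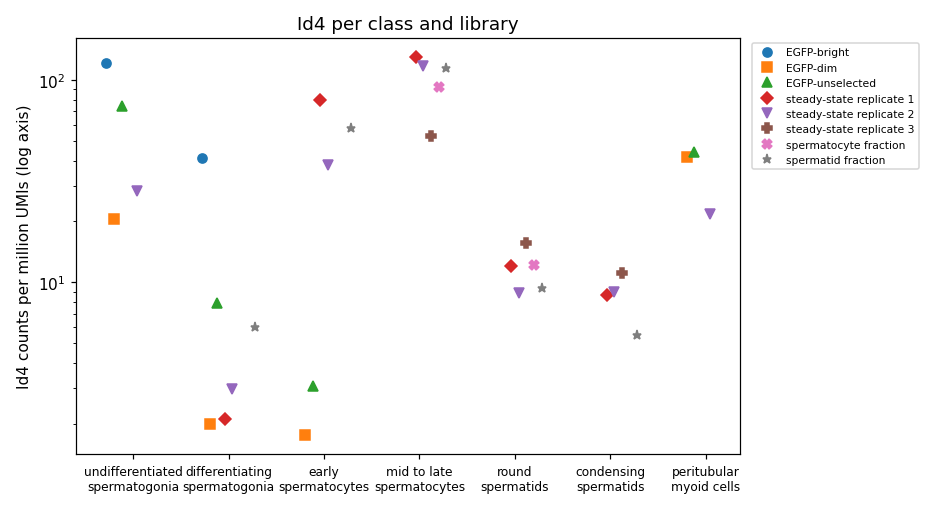
Points give Id4 CPM (log y axis) for each class (x axis) and library with enough cells, and no intervals are drawn. Mid to late spermatocyte-like cells lie between 52.7 and 130.3, undifferentiated spermatogonia-like cells of EGFP-bright at 121.5 and those of EGFP-dim at 20.4.

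The comparison of EGFP-bright with EGFP-dim asks which transcripts go with the level of the stem cell reporter. Genes linked to spermatogonial stem cells stood far higher in EGFP-bright: 16 of 17 measured members of that list were at least 2-fold higher, with a median log2 ratio of 4.34, above all of 10000 random lists of the same size and expression. Among them were Gfra1 (72.7 against 1.09 CPM, log2 ratio 6.07), the transcription factor genes Lhx1 (6.96; 910 against 6 UMIs) and Egr2 (6.42), and Tcl1 (6.57), a coactivator of the kinase AKT. Of 8 progenitor genes 5 were at least 2-fold higher (median 1.68), including the RNA-binding protein genes Nanos3 (2.23) and Lin28a (2.10) and the transcription factor gene Sall4 (2.12). GDNF and FGF signalling genes were higher too, 10 of 19 by at least 2-fold and 2 lower (median 2.58), with Ret, the co-receptor of Gfra1, at 4.68 and Etv4 at 4.62. Nefm, a neurofilament gene, and Irx1, a homeobox gene, reached 7.75 and 7.39.

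Over the whole libraries, genes of chromosome synapsis and recombination leaned to EGFP-dim, while the differentiation list did not stand apart from random lists. Within the undifferentiated class and within clusters 0 and 1, given below, the synapsis lean was far smaller. There the differentiation list lay below nearly all random lists. The differentiation list had a median of −0.37 (percentile 13.5), with Rhox13 at −2.96, Dmrtb1 at −2.76 and the stem cell factor receptor gene Kit at −2.63, while the cyclin gene Ccnd2, also on the list, was at 2.58. Of 35 genes of chromosome synapsis and recombination 20 were at least 2-fold lower in EGFP-bright and 1 higher (median −1.29, below every random list), led by Prdm9 (−4.71), which places meiotic breaks, and the cohesin gene Rec8 (−2.74). The retinoid list had a median of −0.37 (percentile 12.5), in which the retinoic acid-degrading enzyme gene Cyp26b1 stood at −4.99 and the retinoic acid target Stra8 at −1.92. Cell cycle genes had a median of −0.39 (percentile 2.17) and piRNA pathway genes one of 0.45 (percentile 99.8). Within the undifferentiated class both turned, to 0.53 (percentile 100) and −0.30 (percentile 0.02). In cluster 1 these medians were 0.28 and −0.19, and in cluster 0 −0.00406 and −0.0176. The lowest ratios belonged to genes of other cell types: the endothelial genes Cldn5 (−10.09; 10 against 8902 UMIs), Ly6c1 (1 against 3517 UMIs, log2 ratio −12.07 with a counting interval of −17.37 to −9.59) and Esam (1 against 1141), the haemoglobin gene Hba-a1 (1 against 1804; near-identical to Hba-a2) and Ptn (−8.70). Endothelial-like cells were 7.57% of EGFP-dim and 0 of 2579 in EGFP-bright. Early spermatocyte-like cells (340 against 13) and myoid-like cells of cluster 10 (348 against 11) were also more numerous in EGFP-dim. The ratios of the whole libraries thus cannot be read as differences within a cell type.

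Transcripts of haploid cells were also far higher in EGFP-bright. The protamine gene Prm1 (ENSMUSG00000022501; chromosome 16, 10796326 to 10805839), whose product replaces histones in sperm, had 20521 UMIs against 45 (log2 ratio 8.54), the transition protein gene Tnp2 was at 8.28, Prm2 at 7.77, Gsg1 at 7.82 and Smcp at 6.78. The spermatid chromatin list had a median of 6.30 (9 of 13 at least 2-fold higher, 3 lower) and the testis-specific glycolysis enzymes one of 4.96 (7 of 8 higher). Acrosome and flagellum genes had medians of 1.64 and 1.93, which turned to −0.35 and −0.54 with every cell thinned to 2000 UMIs. Condensing spermatid-like cells were 6 of 2579 in EGFP-bright, but held 130128 UMIs. The 2535 spermatogonia-like cells held 10490 UMIs of Prm1, Prm2, Tnp1 and Tnp2 together, fewer than the 20521 of Prm1 alone in the library. A large part of these transcripts thus lay in other barcodes, and the ratios of the whole libraries are not those of spermatogonia. The stress and immediate early list had a median of −0.97 (0 higher, 10 of 20 lower, below every random list), with Hspb1 at −4.38, but 0.77 over the named germ cell classes alone, where Fosb moved from −1.73 to 0.74 and Jun from −1.41 to 0.97. The other medians were: general glycolysis 0.40 (−0.10 with cells scaled to one total and 1.12 over the named germ cell classes), nuclear oxidative phosphorylation −0.40, DNA methylation 0.04, X-linked −0.22, Y-linked 0.05, mitochondrially encoded 0.42, ribosomal proteins 0.21, X genes with autosomal copies −0.39 and those copies 1.10. There is no replicate check on any of these ratios, which compare 2 libraries and not the conditions.

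**Figure D3:**
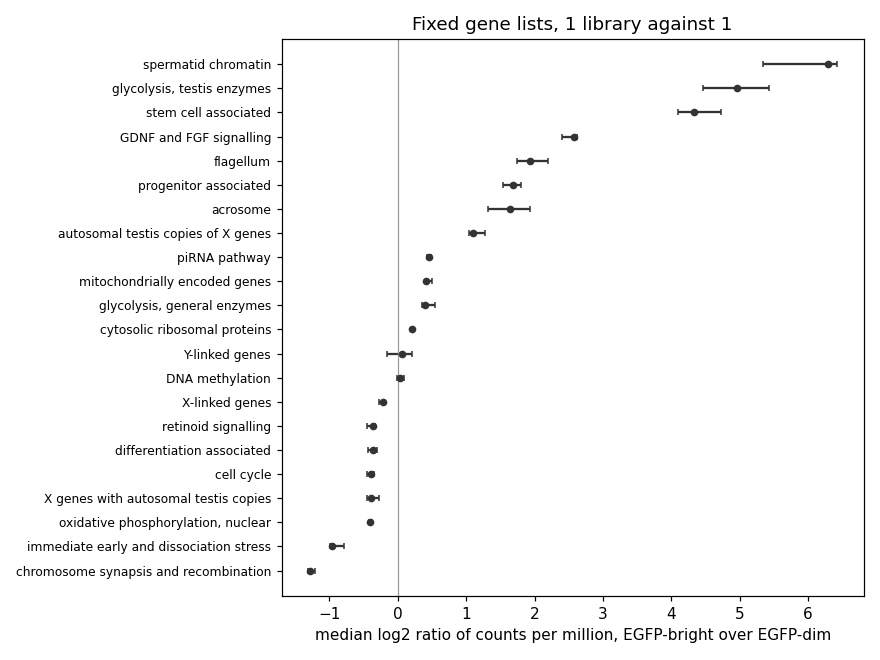
Points give the median log2 ratio of CPM, EGFP-bright over EGFP-dim (x axis), of each fixed gene list (y axis), and bars the 95% interval of 500 Poisson resamples. The spermatid chromatin (6.30), testis glycolysis (4.96) and stem cell lists (4.34) lie farthest to the right and the synapsis list (−1.29) to the left. With thinned cells the acrosome and flagellum medians are negative, but they can rest on fewer members. The stress list turns positive over germ cell classes alone.

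Within the undifferentiated class the stem cell list was still higher in EGFP-bright, with 13 of 16 members at least 2-fold higher and 0 lower (median 2.98), whereas the progenitor list had a median of −1.06 (0 higher, 4 of 8 lower). The GDNF and FGF list had a median of 2.31, and the spermatid chromatin list one of 3.15. Clusters 2 and 1 held the class in EGFP-bright and cluster 1 in EGFP-dim. In cluster 1 alone the medians were 1.14 for stem cell and −0.23 for progenitor genes, of which 0 were 2-fold lower. The latter median had a counting interval of −0.36 to −0.09 and percentile 0.42. The progenitor shift of the class was thus weaker within cluster 1 but still present. In cluster 0, of differentiating cells outside this class, the medians were 3.32 and 0.38 (1 of 8 progenitor genes higher, 0 lower). The EGFP-dim cells of this class also carried the smooth muscle gene Acta2 at 94.4 CPM against 2.52 in EGFP-bright, and they numbered 119. Synapsis and recombination genes had medians of −0.23 in the class (1 of 32 2-fold lower), −0.14 in cluster 1 and −0.19 in cluster 0. In both clusters 0 of them were 2-fold lower. The differentiation list had medians of −0.34 (percentile 0.565), −0.30 (percentile 0.23) and −0.83 (percentile 0) in the same order. Of its members 0 of 7, 0 of 7 and 3 of 9 were 2-fold lower, and 1 was higher in each.

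The first step of germ cell development to be tested was the entry into meiosis, early spermatocyte-like cells (preleptotene to zygotene) against spermatogonia-like cells. Genes of meiotic chromosomes rose: Hfm1, a DNA helicase of crossover formation (chromosome 5, 106840192 to 106926321), went from 7.99 ± 3.19 to 75.2 ± 9.70 CPM (mean ± SD, n = 5 libraries), a log2 change of 3.24 (SE 0.294). Ccdc79, a protein that tethers telomeres to the nuclear envelope, rose by 3.05, the meiotic mismatch repair gene Msh5 by 2.88, the cyclin-like gene Cntd1 by 3.51 and the homeobox gene Pbx3 by 3.65. Among genes that meet the rule for named genes, the largest rise was that of Pparg, a nuclear receptor of lipid metabolism (ENSMUSG00000000440, chromosome 6, 115360951 to 115490399). Its mean went from 1.06 to 30.0 CPM (log2 change 4.75, SE 0.378, edgeR quasi-likelihood adjusted p = 0.000278, higher in 5 of 5 libraries). Gml2 (4.00), Ly6k (3.15), Sdk1 (3.14), Dmrtc2 (2.96) and BC049730 (2.99) also rose in each library. Several of these rises, the largest included, depend on which cells are named early. Pparg did not pass with doublets kept (1.496), the strict cell filter (0.90) or seed 2 (0.86), nor did Sdk1 (1.21, 0.84 and 0.61). Pbx3 did not pass with doublets kept or the strict filter (0.33 with the latter), Msh5 with the strict filter (1.46), Gml2 with doublets kept, resolution 2.0 or seed 2, and BC049730 under 8 other settings.

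Several genes known from spermatogonia fell. Lin28a, an RNA-binding protein of progenitor spermatogonia (chromosome 4, 134003330 to 134018841), went from 24.7 ± 10.7 to 0.832 ± 1.14 CPM (log2 change −4.18, SE 0.470, edgeR quasi-likelihood adjusted p = 0.000797, lower in 5 of 5 libraries). The myosin gene Myh6 (−5.04), Pramef12 (−4.44), the transcription factor genes Egr4 (−4.36) and Pou3f1 (−4.27), the hexokinase gene Hk2 (−4.04), the uridine phosphorylase gene Upp1 (−3.87), Sdc4 (−3.79) and Ddah1 (−3.71) fell as well. Rab26os (−3.69) is an antisense gene, so its value is uncertain. In all, 1255 of 6101 tested genes passed an adjusted p of 0.05 and a 2-fold change, 505 up and 750 down. Class values of 5 libraries entered this test (EGFP-dim, EGFP-unselected, steady-state replicates 1 and 2 and the spermatid fraction), because steady-state replicate 3 had under 20 early spermatocyte-like cells and the planned fit of the 3 steady-state libraries could not be made.

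Among the fixed lists, 14 of 25 synapsis and recombination genes rose and 0 fell, and 14 rose adjusted over the list alone (median 1.12, camera adjusted p = 1.33e-08 and adjusted p = 0.604 with an estimated correlation). Where no other number is given below, the counts adjusted over the list alone are the same. Hormad2, of the unsynapsed chromosome axis, rose by 2.45. Of 5 progenitor genes 4 fell, as they did adjusted over the list alone (median −1.63, camera adjusted p = 0.0104, adjusted p = 0.714 with an estimated correlation), with Sox3 at −1.50. Of 9 GDNF and FGF genes 3 fell, and 5 adjusted over the list alone (median −1.36, camera adjusted p = 0.0314, adjusted p = 0.714 with an estimated correlation). Of 15 general glycolysis genes 7 fell (median −0.92, camera adjusted p = 0.00891, adjusted p = 0.604 with an estimated correlation), among them Aldoc (−2.71), Pgam1 (−2.17) and Aldoa (−1.54). Of 33 cell cycle genes 10 fell and 4 rose, and 11 and 4 adjusted over the list alone (median −0.50, camera adjusted p = 0.143), with the centromere histone gene Cenpa (−3.41), the cyclin gene Ccna2 (−2.64) and the mitotic kinase gene Plk1 (−2.35, but 0.0426 with doublets kept) falling. Of 4 DNA methylation genes 2 fell, Tet3 (−1.34) and Dnmt3a (−1.32), and 3 adjusted over the list alone (camera adjusted p = 0.0415, adjusted p = 0.714 with an estimated correlation). Of 20 piRNA pathway genes 1 rose (Gpat2, 1.32) and 2 fell, Henmt1 (−2.03) and Tdrd1 (−1.10, but 0.12, 0.36 and 0.64 at resolution 2.0, with seed 2 and with the strict cell filter), while the median was 0.49 (camera adjusted p = 0.0197, adjusted p = 0.714 with an estimated correlation). Of 9 retinoid genes 2 rose, among them the retinoic acid-making enzyme gene Aldh1a2 (1.08), and 2 fell, with a camera adjusted p of 0.786. The 18 stress genes held 6 that fell, 8 adjusted over the list alone (median −0.66, camera adjusted p = 0.0312, adjusted p = 0.714 with an estimated correlation), including Klf6 (−1.78). Of 86 ribosomal protein genes 6 fell and 0 rose (median −0.26, camera adjusted p = 0.00160, adjusted p = 0.714 with an estimated correlation). None of the 8 testis glycolysis, 11 acrosome or 13 mitochondrially encoded genes passed, nor did the 1 tested differentiation gene. Of the genes named here Henmt1 did not pass at resolution 2.0, with seed 2 or with the strict filter (−0.56, −0.36 and −0.29). Cenpa, Ccna2, Plk1 and Gpat2 did not pass at resolution 2.0, with doublets kept or with seed 2, and Klf6 with these or the strict filter. Sox3, Tet3, Dnmt3a, Tdrd1 and Aldh1a2 each lost the threshold under 4 or more other settings, some by leaving out 1 library.

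This step differed between kinds of library. In the sorted libraries alone 1957 of 6896 genes passed, and in the steady-state and spermatid fraction libraries alone 1746 of 5190. Of 4807 genes tested in both, 599 passed in both, 562 in the same direction and 37 in opposite directions, where independent lists would share 392. The change itself differed between the 2 kinds of library for 1610 of 6101 genes (interaction term, edgeR quasi-likelihood, adjusted p under 0.05 and at least 2-fold). For X-linked genes the pooled median was −0.28 (33 rose and 58 fell of 401, 34 and 86 with DESeq2, 33 and 50 adjusted over the list alone; camera adjusted p = 0.0213, adjusted p = 0.772 with an estimated correlation), but 0.15 in the sorted libraries and −0.92 in the others. The flagellum list had medians of −0.60 and 0.47 in the same order, and 0.41 pooled, where Rsph1 (1.96, adjusted p = 0.0797, edgeR quasi-likelihood) and Ccdc39 (1.09, adjusted p = 0.277) missed the threshold. In the sorted libraries alone these 2 genes were at −2.59 and −3.11. Of the DNA methylation genes 0 of 6 fell in the sorted libraries (median −0.44) and 3 of 4 in the others (−2.27). The piRNA list had 2 up and 4 down of 20 (median 0.00571) in the sorted libraries and 8 up and 1 down of 19 (0.87) in the others, the stress list medians of −0.35 and −2.19, and the X genes with autosomal copies 0.24 and −1.11. Ribosomal protein genes showed 1 up and 2 down of 86 (median −0.04) in the sorted libraries and 2 up and 12 down of 85 (−0.37) in the others. The GDNF and FGF genes showed 1 up and 4 down of 12 (−0.69) and 0 up and 4 down of 5 (−3.11), and the autosomal copies of X genes 0 up and 2 down of 10 (−0.21) and 5 up and 0 down of 12 (0.74). Cluster 9 held the early class in the sorted libraries and cluster 24 in the others. The spermatogonia side differed as well, mostly clusters 0, 1 and 8 in the sorted libraries and cluster 3 in the others.

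The next step ran from early to mid to late spermatocyte-like cells, over the 3 libraries with 20 cells of both classes (steady-state replicates 1 and 2 and the spermatid fraction), again because the planned fit could not be made. X-linked genes fell as a body. Of 344 tested, 246 fell and 3 rose, with a median log2 change of −4.06, and the 10 largest falls of all named genes were X-linked. The homeobox gene Rhox1 (chromosome X, 37213804 to 37222258) went from 90 UMIs to 0, at least 316-fold lower against a floor of 3 counts over the group, and Xlr3c from 46 UMIs to 0, at least 161-fold lower. Rhox and Xlr genes have near-identical copies, so their counts are uncertain. Hprt, an enzyme of purine salvage, fell by 8.66 on the log2 scale (93.4 ± 18.4 to 0.114 ± 0.0987 CPM, n = 3, edgeR quasi-likelihood adjusted p = 1.27e-14, lower in 3 of 3 libraries), and Rpl39 by 8.66. The fall of Hprt was −4.45 with the strict cell filter and −4.88 with seed 2, still past the threshold, so the size of the X-linked fall depends on which cells are named early. The X-linked list had a camera adjusted p of 8.02e-23, and an adjusted p of 0.714 with an estimated correlation; its mean was −3.86. Of 12 X-linked genes with autosomal testis copies 12 fell (median −5.99, −5.80 with unseen genes at their bound, camera adjusted p = 2.38e-06, adjusted p = 0.604 with an estimated correlation), including Tktl1, with 78 UMIs in the early class and 2 in the later one. Of the 12 autosomal copies 7 rose and 0 fell (median 1.09, but 0.37 with 2 up and 1 down under library size scaling; camera adjusted p = 0.0580), such as Fam50b (3.76), Cetn1 (3.52) and Pgk2 (1.43, but 0.71 and not passing under that scaling).

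Flagellum and acrosome genes rose in the same step. Of 26 flagellum genes 23 rose and 0 fell (median 2.57, camera adjusted p = 9.29e-06, adjusted p = 0.604 with an estimated correlation), among them Ccdc40 (5.06), Spag16 (4.12), Tcte1 (3.97) and the dynein gene Dnah17 (3.71). Acrosome genes rose in 7 of 11 cases (median 2.47, camera adjusted p = 0.00744, adjusted p = 0.714 with an estimated correlation), with Zpbp2 at 3.61 and Acrbp at 3.42. Testis-specific glycolysis enzymes rose in 6 of 8 (median 2.89, camera adjusted p = 0.00891, adjusted p = 0.714 with an estimated correlation), and Ldhc, the testis lactate dehydrogenase, went from 1074 ± 96.0 to 8826 ± 485 CPM. Of 43 nuclear oxidative phosphorylation genes 11 rose and 4 fell (median 0.75, but 0.03 with 1 up and 7 down under library size scaling; camera adjusted p = 0.00145, adjusted p = 0.714 with an estimated correlation). Spermatid chromatin genes showed 1 up and 3 down of 9 (median −0.90, but 0 up and 7 down with −1.63 under library size scaling; camera adjusted p = 0.0728). Prm1, Prm2, Tnp1 and Tnp2 took a mean of 0.592% of UMIs in early and 0.315% in mid to late spermatocytes of steady-state, so spermatid RNA from outside these cells would move this list the same way. The monoglyceride lipase gene Mgll (6.74), the aquaporin gene Aqp9 (5.41) and the secreted factor gene Prok2 (5.14) were among the largest rises, but Mgll did not pass with the strict filter (0.86) or seed 2 (0.92), nor Prok2 with these (0.19 and 0.15) or at resolution 2.0 (0.66). Speer1, from a multicopy family, went from 0 UMIs in the early class to 813, at least 25.8-fold higher. Ttll1 and Slc13a5 had 2 and 1 UMIs in the early class, and their ratios of summed counts were 79.9 (log2 interval 4.47 to 9.37) and 81.6 (3.87 to 11.65).

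Synapsis and recombination genes fell in 16 of 26 cases and rose in 1 (median −1.62, camera adjusted p = 0.000785, adjusted p = 0.650 with an estimated correlation), with the X-linked Tex11 at −6.78, Tex15 at −5.87 and Zcwpw1 at −2.62. Cell cycle genes fell in 16 of 33 and rose in 6 (median −0.82, camera adjusted p = 0.0244, adjusted p = 0.714 with an estimated correlation), led by the replication helicase genes Mcm4 (−4.65) and Mcm5 (−3.28). Mitochondrially encoded genes fell in 9 of 12 (median −1.28, camera adjusted p = 6.83e-07, adjusted p = 0.714 with an estimated correlation). Of 15 Y-linked genes 7 fell (median −1.26, camera adjusted p = 0.00744, adjusted p = 0.714 with an estimated correlation), such as Ddx3y (−6.08) and Zfy1 (−5.60). Of 20 piRNA genes 9 rose and 2 fell (median 0.70, −0.02 under library size scaling, camera adjusted p = 0.206), with Tdrd6 at 4.07, Henmt1 at 3.31 and Tdrd1 at 2.48, the last of which turned to −0.34, −0.69 and −0.66 at resolution 2.0, with seed 2 and with the strict cell filter. Ribosomal protein genes showed 5 up and 6 down of 85, with a median of 0.02, a mean of −0.27 and a camera direction that was down (adjusted p = 0.471). Under library size scaling 0 of them rose and 24 fell (median −0.69), and cell cycle genes showed 1 up and 22 down, flagellum genes 20 and 3, acrosome genes 6 and 1 and testis glycolysis genes 5 and 1. In all, 3261 of 6391 genes passed, 1895 up and 1366 down. Under library size scaling alone 3593 passed, 1181 up and 2412 down, and the median of all genes moved from 0.10 to −0.62, so changes are relative to the TMM scale.

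Round spermatid-like cells were set against mid to late spermatocyte-like cells in the 3 steady-state libraries, as planned. Sex-linked genes rose. Of 394 X-linked genes 306 rose and 1 fell, 315 and 2 adjusted over the list alone (median 3.88, 3.87 with unseen genes at their bound, camera adjusted p = 6.54e-22, adjusted p = 0.714 with an estimated correlation), and of 69 Y-linked genes, many in multicopy families, 65 rose, 66 adjusted over the list alone (median 4.31, 4.27 with unseen genes at their bound, camera adjusted p = 8.71e-12, adjusted p = 0.714 with an estimated correlation). Cstf2 (5.36) and Utp14a (4.70) led the X-linked genes with autosomal copies, 9 of 11 of which rose (camera adjusted p = 0.00851, adjusted p = 0.714 with an estimated correlation). Their autosomal copies showed 2 up and 1 down of 12, a median of −0.15 and a mean of 0.16 (camera adjusted p = 0.717). Among the largest rises were the desmosomal cadherin gene Dsg1a (7.06, SE 0.422, edgeR quasi-likelihood adjusted p = 0.00113, higher in 3 of 3 libraries; chromosome 18, 20310811 to 20343350), the dynein gene Dnah9 (6.73), the transcription factor gene Klf17 (6.61), the exchange factor gene Vav3 (6.64), Mageb5 (6.83), Cpa6 (6.66), Cngb3 (6.55) and Tmem144 (170.0 ± 55.1 against 2.03 ± 0.673 CPM). Pard3bos1 (7.11) is an antisense gene and uncertain.

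Of the largest falls, Anp32b fell by 5.36 on the log2 scale (SE 0.746, edgeR quasi-likelihood adjusted p = 0.00360, lower in 3 of 3 libraries), Mllt10, a cofactor of histone methylation, by 4.98, the replication licensing inhibitor gene Gmnn by 4.92, and Alyref, of mRNA export, by 4.69. piRNA pathway genes fell in 12 of 20 cases and rose in 0, 12 and 1 adjusted over the list alone (median −1.49, camera adjusted p = 0.00635, adjusted p = 0.714 with an estimated correlation), including Tdrd5 (−4.26) and Mov10l1 (−3.02). Nuclear oxidative phosphorylation genes fell in 13 of 43, 12 adjusted over the list alone (median −0.79, camera adjusted p = 1.57e-05, adjusted p = 0.721 with an estimated correlation), and mitochondrially encoded genes in 10 of 12, 11 adjusted over the list alone (median −1.82, camera adjusted p = 0.000133, adjusted p = 0.714 with an estimated correlation). Ribosomal protein genes fell in 18 of 85 and rose in 1, but in 5 and 1 adjusted over the list alone (median −0.71, camera adjusted p = 5.24e-07, adjusted p = 0.721 with an estimated correlation). Cell cycle genes fell in 13 of 30 and rose in 2 (camera adjusted p = 0.0413, adjusted p = 0.714 with an estimated correlation), where Cdk1 was at −2.43 and Ccnd3 at 4.44. Synapsis and recombination genes split, 5 up and 7 down of 23 (median −0.83, camera adjusted p = 0.243). Spermatid chromatin genes rose in 5 of 9 (median 3.16, camera adjusted p = 0.206), with the linker histone genes Hils1 (5.05) and H1fnt (4.92) and the remodeller gene Chd5 (5.09). Flagellum genes split, 8 up and 5 down of 26 (median 0.22), with Odf3 at 5.96 and Akap4 at 4.57. Stress genes rose in 6 of 11 and fell in 2 (median 3.97, camera adjusted p = 0.247), among them Nr4a1 (5.07) and Klf4 (4.30).

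In all, 4169 of 7419 genes passed, 2408 up and 1761 down, and library size scaling moved the median of all genes from −0.03 to −0.25. Under it 37 ribosomal protein genes fell and 1 rose, and 21 nuclear oxidative phosphorylation genes fell. The number was 2694 without replicate 1 (1890 up, 804 down), 2436 without replicate 2 (1815 up, 621 down) and 5151 without replicate 3, whose class came from cluster 16. With spermatocytes of cluster 22 alone, a choice made after seeing the data, 5242 passed.

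Condensing spermatid-like cells were then set against round ones in the same 3 libraries. General glycolysis genes rose in 11 of 14 cases and fell in 2 (median 1.99, 0.59 under library size scaling, camera adjusted p = 0.00777, adjusted p = 0.714 with an estimated correlation), led by Gpi1 (3.78), the pyruvate kinase gene Pkm (2.87) and Hk1 (2.40, but 0.99 and not passing under library size scaling). Glul, the glutamine synthetase gene (chromosome 1, 153899944 to 153909723), went from 134.2 ± 53.1 to 1188 ± 47.6 CPM (log2 change 4.62, SE 0.220, edgeR quasi-likelihood adjusted p = 1.03e-09, higher in 3 of 3 libraries). The lipid carrier gene Apoe (4.98), Cby3 (4.95), Efcab1 (4.76) and Fam214b (4.71) rose too. Klk1b3 (5.22) and Klk1b26 (4.65) belong to a kallikrein family of near-identical genes, and Ppp2r2cos, Itpr3os and Rsf1os1 (4.99, 4.77 and 4.63) are antisense genes, so these are uncertain. Nuclear oxidative phosphorylation genes went both ways, 6 up and 7 down of 43 (median −0.29). Acrosome genes fell in 9 of 11 and rose in 1 (median −2.01, camera adjusted p = 0.00583, adjusted p = 0.714 with an estimated correlation), such as Zp3r (−2.85) and Zpbp (−2.71). The tumour necrosis factor receptor gene Cd27 fell by 4.36 (SE 0.307, edgeR quasi-likelihood adjusted p = 1.51e-08, lower in 3 of 3 libraries; chromosome 6, 125232622 to 125237010), the tubulin glycylase gene Ttll3 by 3.81 and the transcription factor gene Arid3a by 3.77.

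Y-linked genes fell in 55 of 67 cases and rose in 5 (median −2.49, −2.39 with unseen genes at their bound, camera adjusted p = 8.55e-07, adjusted p = 0.604 with an estimated correlation), while X-linked genes went both ways, 121 up and 159 down of 380, 121 and 161 adjusted over the list alone (median −0.70, mean −0.21, camera adjusted p = 0.733). Ribosomal protein genes rose in 49 of 85 and fell in 1 (median 1.26, camera adjusted p = 8.44e-11, adjusted p = 0.714 with an estimated correlation), but under library size scaling 2 rose and 19 fell, with a median of −0.15. Spermatid chromatin genes showed 5 up and 2 down of 7 (median 1.35, −0.05 under library size scaling, camera adjusted p = 0.0559), with Tssk6 at 4.16 and H2afb1 at 3.89. Testis glycolysis genes showed 4 up and 1 down of 8 (median 0.78, −0.62 under library size scaling, camera adjusted p = 0.318), with Pgk2 at 2.35 (0.95 and not passing under that scaling). The mitochondrially encoded list had 1 gene up of 12 (median 0.66, −0.75 under library size scaling, camera adjusted p = 0.0413, adjusted p = 0.762 with an estimated correlation). Flagellum genes fell in 12 of 26 and rose in 3 (camera adjusted p = 0.140), where Fsip2 was at −3.15 and Akap4 at 2.86. In all, 3585 of 6601 genes passed, 1638 up and 1947 down. Under library size scaling X-linked genes showed 61 up and 233 down, general glycolysis genes 4 and 3, testis glycolysis genes 0 and 4, nuclear oxidative phosphorylation genes 0 and 32 and flagellum genes 2 and 19. Library size scaling gave 4752 genes in all, 609 up and 4143 down, and moved the median of all genes from −0.19 to −1.59. Spermatid marker transcripts (Prm1, Prm2, Tnp1 and Tnp2) took 19.6% ± 0.839 of UMIs in condensing and 2.12% ± 0.572 in round cells, so a rise here is relative to most other genes and the size of each change depends on the scaling.

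The share of UMIs on X-linked genes followed the same course when read directly from the counts. In the steady-state libraries it was 0.143% ± 0.131 (SD, n = 3) in mid to late spermatocytes, 1.34% ± 0.0870 in round and 1.47% ± 0.0429 in condensing spermatids. The single mid to late values were 0.0596%, 0.0750% and 0.293%, the last from replicate 3, where cluster 16 held the class. The spermatocyte fraction showed 0.0258% (0.0255 to 0.0261) in the same class and the spermatid fraction 0.153%. Undifferentiated spermatogonia had 1.78% in EGFP-bright, 1.70% in EGFP-dim and 1.76% in EGFP-unselected, and differentiating ones 1.76%, 2.24% and 2.19% in the same order, with 1.88% in steady-state replicates 1 and 2. Differentiating cluster 8, which takes the early spermatocyte name under other settings, had 2.34%, and differentiating cluster 0 had 1.75%. Early spermatocytes differed by kind of library, with 2.63% in EGFP-dim and 2.67% in EGFP-unselected (cluster 9), and 1.02%, 1.34% and 1.03% in steady-state replicates 1 and 2 and the spermatid fraction (cluster 24). The latter values hold for the main clustering only: the mean of replicates 1 and 2 was 1.18%, but 0.456% at resolution 2.0, 0.502% with doublets kept, 0.224% with the strict cell filter and 0.231% with seed 2. With the strict filter early cells of replicates 1 and 2 ranged from 0.194% to 0.255%, and with seed 2 from 0.189% to 0.272%. Mid to late cells of all 3 replicates ranged from 0.0574% to 0.245% and from 0.0599% to 0.258%, so the ranges overlap. Replicate 3 enters the mid to late range only, so this overlap does not compare the classes within a library. Y-linked genes took 0.00704% ± 0.00869 in mid to late spermatocytes, 0.0787% ± 0.00229 in round and 0.0157% ± 0.000296 in condensing spermatids.

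**Figure D4:**
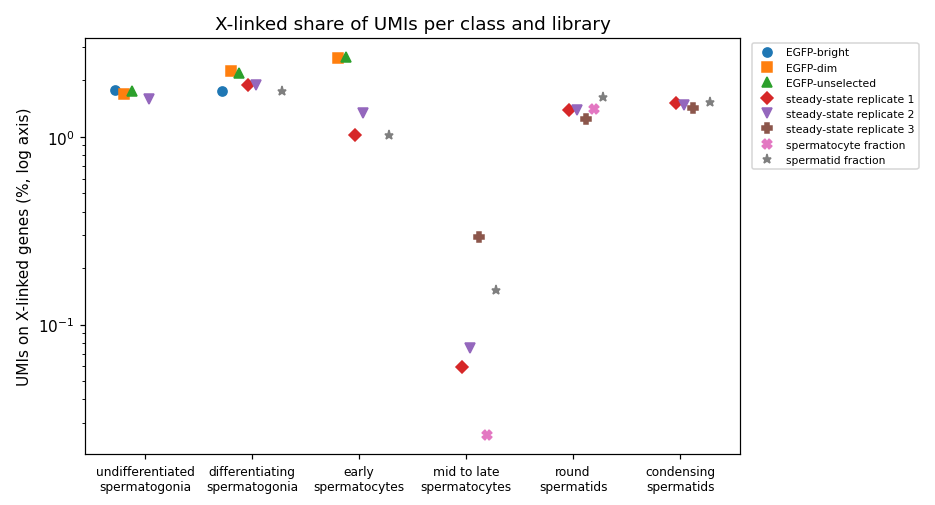
Points give the percent of UMIs on X-linked genes (log y axis) for each class (x axis) and library with at least 20 cells, and no intervals are drawn. Mid to late spermatocyte-like cells lie between 0.0258% and 0.293%, and early spermatocyte-like cells between 1.02% and 1.34% in 3 libraries and 2.63% and 2.67% in 2, of which the lower range holds for the main clustering only.

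The spermatid and spermatocyte fractions, 1 library each, were compared over all barcodes. Among the higher ratios in the spermatid fraction were the ketone body enzyme gene Oxct2b at a log2 value of 5.49, the carbonic anhydrase gene Car2 at 5.45, Cabs1 at 5.27, Prm2 at 5.09 and Akap4 at 4.87. Sex-linked genes were higher as a body, 339 of 346 X-linked genes by at least 2-fold (median 4.34) and 48 of 48 Y-linked genes (median 4.45), both above every random list. The spermatid chromatin list had a median of 4.65 (10 of 12 higher), the acrosome list 4.17 (9 of 17 higher, 1 lower) and the X genes with autosomal copies 3.78 (9 of 9). Lower in the spermatid fraction were Slc24a5, a potassium-dependent sodium and calcium exchanger (−2.98), Marf1 (−2.92), the spermatocyte regulator Mybl1 (−2.41), the hormone precursor gene Pomc (−2.37) and Id4 (−1.30). The piRNA list had a median of −0.92 (10 of 22 lower, 1 higher, percentile 0.75), the nuclear oxidative phosphorylation list −0.64 and the ribosomal proteins −0.66. The flagellum list was at 0.19, and at −0.04 under TMM scaling. The differentiation list had a median of 2.49, but −0.45 with cells thinned to 2000 UMIs, and differentiating spermatogonia-like cells were 7.46% of the spermatid fraction. TMM factors shifted every log2 ratio by 0.23.

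In the comparison of EGFP-bright with the spermatocyte fraction, again 1 library each, stem cell and progenitor genes stood far higher in EGFP-bright. Of 17 stem cell genes 16 were at least 2-fold higher in EGFP-bright (median log2 ratio 8.25), as were 8 of 8 progenitor genes (9.40) and 18 of 18 GDNF and FGF genes (7.73). The forkhead gene Foxf1 had 4858 UMIs against 5 (log2 ratio 11.64), Tcl1 3605 against 5 (11.21) and the X-linked Sox3 2682 against 8 (10.10), while the zinc finger gene Zic1 had 1502 against 1 (12.27, counting interval 9.79 to 17.57). X-linked genes were higher in 427 of 504 cases and lower in 59 (median 6.94), and the X genes with autosomal copies in 13 of 13 (7.76), whereas the autosomal copies had a median of −1.26 (1 higher, 7 of 12 lower). Flagellum (−4.25, 28 of 29 lower), acrosome (−3.15, 15 of 17 lower) and testis glycolysis genes (−5.00, 8 of 9 lower) stood higher in the spermatocyte fraction, with Crisp2 at −6.46 and Ldhc at −7.56. The potassium channel gene Kcnj9 had 4 UMIs in EGFP-bright against 9080 (−9.43), and Zmynd10, a factor of dynein arm assembly, was at −8.97. Synapsis and recombination genes went both ways, with 16 of 35 at least 2-fold higher in EGFP-bright and 8 lower (median 0.20, −0.75 under TMM scaling). Mitochondrially encoded genes were higher in EGFP-bright (3.13), and ribosomal proteins at 1.29 (0.35 under TMM scaling). TMM factors shifted every log2 ratio here by 0.94, and no ratio has a replicate check.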

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

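All tests in this part were chosen after the result they address was seen, and only for those on droplets, on transcription in EGFP-bright spermatogonia and on a gene that overlaps Id4 was the prediction written before the value of the test was known.

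The change from spermatogonia to early spermatocytes differed between sorted and other libraries for 1610 of 6101 genes by a test of the difference itself (interaction term, edgeR quasi-likelihood, adjusted p under 0.05 and at least 2-fold), 1030 higher and 580 lower in the sorted libraries. Of 401 X-linked genes 184 were higher and 6 lower in that term. Free spermatid RNA in the droplets was 1 possible cause of the lower X share. Spermatid RNA in early spermatocytes exceeded that in spermatogonia by a mean of 0.164 percentage points (range over 3 libraries 0.115 to 0.241). This is far under the 30 points this explanation calls for, which argues against it. Free RNA of mid to late spermatocytes, with a steady-state X share of 0.143%, was not tested. Cells of different steps under the same name are another explanation. For this, 10 DNA replication genes had a median log2 ratio of 1.00 in cluster 9 over cluster 24 (range −0.67 to 2.15). This just meets the threshold of 1 and would go with earlier cells in the sorted libraries. The spermatogonia also came from different clusters, mostly 0, 1 and 8 in the sorted libraries and 3 in the others. Kind of library goes with the sort, the preparation and the depth, so these data cannot separate them.

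Spermatid transcripts stood high in spermatogonia-like cells of EGFP-bright, with 10490 UMIs of Prm1, Prm2, Tnp1 and Tnp2 over 2535 cells and at least 1 in 88.4% of them. A spermatid caught in the same droplet would put most of these in few cells: the 5% of cells with most held 47.2%, between the 50% and 30% set for and against this, where Poisson counting alone would give 10.7%. Free spermatid RNA in the suspension would raise spermatid genes as a body, and 88% of 50 such genes (44) were at least 2-fold higher in EGFP-bright than in EGFP-dim spermatogonia-like cells, consistent with free RNA but also with the other explanations. Transcription in the spermatogonia would spare somatic cells of the library, which held 0.341 times the UMIs per cell (Poisson 95% interval 0.219 to 0.508, 17 cells), so this stays open. The spermatid transcripts of EGFP-bright may thus come from outside the spermatogonia, and their ratios there say nothing of gene activity.

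Id4 RNA stood at 52.7 to 130.3 CPM in mid to late spermatocyte-like cells, against 102.5 in the whole EGFP-bright library. Over all libraries the undifferentiated clusters 2 and 1 held 169.7 and 41.7 CPM. Free RNA from spermatogonia could carry it there only with other spermatogonial transcripts, but the other 11 undifferentiated markers over Id4 stood at 0.0132 times (0.0122 to 0.0142) their level in cluster 2 of EGFP-bright, which argues against it. An annotated gene over an Id4 exon could take its reads, and 2 such genes exist, both on the opposite strand and neither over the last exon. They cover 171 of 3849 Id4 exon bases, and the 1 of them that was counted had 34 UMIs against 11259 for Id4 in these cells, but with read positions unknown this stays open. Id4 stood above round spermatids by at least 3.37 times in 5 libraries, but this restates the pattern and cannot test transcription in these cells, which stays open. Id4 RNA says nothing here of ID4 protein.

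Other splits of the class sums were counted beside the tests. Each of them mixes both classes within a group, so the class difference itself adds to the spread. Their numbers therefore do not show how many genes would pass without a class difference, and no conclusion is drawn from them. For early spermatocytes against spermatogonia, 1 of 100 splits, the real one, gave as many genes as 1255, and the highest other gave 1228. This number came from 2 splits that each parted the classes in 3 of the 5 libraries, and its cause was not tested. In each of the other 3 contrasts 1 of 10 splits, again the real one, reached the real number and the highest other gave 0, but 10 splits cannot give a share under 0.05.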

How the results depend on the processing

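The tests of this part repeat each result under choices fixed before the data were examined, and those named as added were chosen after. Which list medians were followed here was also chosen after their values were seen. Of the values that answer a comparison, 138 were the same under another setting and 88 moved. Of all other values 6019 were the same, 230 became weaker, 103 stronger, 1041 moved and 38 reversed. For a tested gene the same means the same side of the threshold, and genes that passed in neither setting may have changed direction. Numbers of genes had to stay within a set fold. Shares and ratios had to stay within the counting interval of the main value, and steady-state means within their SD. Where no cause is given below, the cause was not tested. Depth limits what single libraries can show: rare transcripts of EGFP-unselected, the shallowest library, are seen least. Steady-state replicate 3 could not enter the first 2 contrasts, so leaving it out there gave no value, nor did mid to late against early spermatocytes at resolution 0.5.

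Numbers of genes that passed. As an added choice, leaving out 1 library gave 958 to 1240 for early and 2705 to 3264 for mid to late spermatocytes. As planned, it gave 2436 to 5151 for round and 3423 to 3490 for condensing spermatids. Without the replicate block 918, 3045, 4157 and 3431 passed. For early spermatocytes 2019 passed with no fold threshold, 744 with the strict cell filter and, as an added choice, 1957 in the sorted libraries alone. At resolution 0.5 no steady-state or spermatid fraction cell was named early spermatocyte, so its 1961 genes also rest on the sorted libraries alone and differ from the main result in 2 ways at once. With seed 2, where fewer genes could be tested, 499, 1550, 2501 and 2054 passed in the 4 contrasts. Of 32 list results by camera 0 were left with an estimated correlation.

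Reversed values, early spermatocytes. Resolution 0.5, again with the sorted libraries alone, turned Ccdc39 to −3.10, Jund to 0.0224, Rdh11 to −1.49, Rpl36a to 0.00362 and Rsph1 to −2.58, and the sorted libraries alone (added) gave −3.11, 0.0207, −1.40, 0.00694 and −2.59 for the same genes. Tdrd1 turned to 0.12 at resolution 2.0, 0.36 with seed 2 and 0.64 with the strict filter. With doublets kept Gm1141 turned to 0.17 and Plk1 to 0.0426, with seed 2 Cmc4 to −0.28, and with the strict filter Zfy1 to −0.0799.

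Reversed values, later steps. In mid to late spermatocytes Tdrd1 turned to −0.34 at resolution 2.0, −0.69 with seed 2 and −0.66 with the strict filter, and Rrm2 to 1.48 with doublets kept, 0.0547 at resolution 2.0, 2.52 with seed 2 and 2.09 with the strict filter. Pdha2 turned to −0.13 with seed 2 and −0.0983 with the strict filter. In condensing spermatids library size alone turned Atp5g1 to −0.0319, Dusp4 to −0.35 and mt-Nd1 to −0.0544, by the shift of all genes.

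Class shares. Undifferentiated cells of EGFP-bright were 92.6% with doublets kept, 96.9% at resolution 0.5, 75.5% at 2.0, 64.9% with seed 2 and 91.9% with the strict filter. Differentiating cells of EGFP-dim were 10.3%, 38.4%, 11.3% and 9.22% under the first 4 of these, and of EGFP-unselected 6.53%, 27.0%, 8.89%, 5.15% and 30.5%. Mid to late spermatocytes of the spermatocyte fraction were 76.3% at resolution 2.0, 76.9% with seed 2 and 60.1% with the strict filter. Round spermatids of the spermatid fraction were 32.0% with doublets kept, 37.8% at resolution 0.5 and 37.7% with seed 2, and its condensing ones 18.5% at 2.0, 18.7% with seed 2 and 18.6% with the strict filter. The steady-state mean of mid to late spermatocytes was 28.3%, 25.9%, 20.6%, 21.7% and 20.6% under the 5 settings, and that of early ones 3.30%, 0, 6.88%, 5.33% and 5.76%.

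X share. In steady-state early spermatocytes it moved most, from a mean of 1.18% to 0.456% at resolution 2.0, 0.502% with doublets kept, 0.224% with the strict filter and 0.231% with seed 2. With doublets kept it was 2.43% in EGFP-dim early spermatocytes, 0.0296% in mid to late ones of the spermatocyte fraction, 1.82% in round spermatids of the spermatid fraction and 1.57% in those of steady-state. Resolution 0.5 gave 0.0264% in mid to late cells of the spermatocyte fraction and 1.66% in round ones of the spermatid fraction, resolution 2.0 gave 2.44%, 0.0248% and 1.59% for early, mid to late and round cells of these libraries, seed 2 gave 2.43%, 0.0247% and 1.61%, and the strict filter 0.0269% and 1.59% for the last 2.

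Pairs of single libraries, median log2 ratios. TMM gave, for spermatid over spermatocyte fraction, 4.42 for spermatid chromatin, 3.94 for acrosome and 4.10 for X-linked genes, and for EGFP-bright over the spermatocyte fraction 7.31 for stem cell, −5.19 for flagellum and 6.00 for X-linked genes. At 20 UMIs these were 4.49 for spermatid chromatin and 4.10 for X-linked genes in the first pair, and 6.29 for X-linked and −0.64 for Y-linked genes in the second. Thinned to 2000 UMIs, EGFP-bright over EGFP-dim gave 3.92 for stem cell, 1.91 for progenitor, −0.21 for differentiation, −0.35 for acrosome and −0.54 for flagellum genes. Thinned cells also gave −0.45 for differentiation, −1.39 for GDNF and FGF, −0.94 for retinoid, 4.18 for spermatid chromatin, 3.61 for acrosome and 4.17 for X-linked genes in spermatid over spermatocyte fraction, and 6.37 for stem cell, −4.85 for flagellum and 6.29 for X-linked genes in EGFP-bright over the spermatocyte fraction. Equal cell totals gave −0.25 for differentiation and 5.19 for spermatid chromatin in bright over dim, 4.00 for spermatid chromatin, 3.85 for acrosome and 4.05 for X-linked genes in spermatid over spermatocyte fraction, and −4.76 and 6.06 for flagellum and X-linked genes in the last pair. Germ cell classes alone (added) gave, bright over dim, 5.00 for stem cell, 1.498 for progenitor and −0.53 for differentiation genes, 0.74 for Fosb, 0.97 for Jun and 1.04 for Ldhb, then 4.90, 4.47 and 4.68 for spermatid chromatin, acrosome and X-linked genes, and 8.40, −4.84 and 7.50 for stem cell, flagellum and X-linked genes in the other pairs. Thinned to 1000 UMIs, 9.60% of EGFP-bright cells had an Id4 UMI.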

Other observations

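The values in this part carry no test except those of Dnmt3l and Uhrf1, which come from the tests of the report, and the genes and clusters in it were chosen after their values were seen.

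Id4 RNA was not limited to germ cells. Peritubular myoid-like cells, the contractile cells around the tubule, held 41.5 CPM in EGFP-dim (Poisson 95% interval 33.5 to 50.8) and 44.2 in EGFP-unselected (36.0 to 53.8), where differentiating spermatogonia-like cells held 1.99 and 7.88. Early spermatocyte-like cells held 1.76 CPM in EGFP-dim and 3.09 in EGFP-unselected, but 79.99 in steady-state replicate 1 (68 UMIs), 38.0 in replicate 2 and 58.2 in the spermatid fraction. Dnmt3l, a cofactor of DNA methylation, rose by 4.36 on the log2 scale from mid to late spermatocytes to round spermatids (SE 0.904, edgeR quasi-likelihood adjusted p = 0.0112, higher in 3 of 3 libraries), while Uhrf1, which guides maintenance methylation, fell by 1.78.

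Cluster 25, left unnamed, held 130 cells, 96.2% of them from steady-state replicate 3, and its leading genes were the Sertoli cell genes Cst9, Defb19, Cst12, Rhox8, Aard and Amhr2. Cluster 19, with 457 cells and leading genes Cst9, Cst12 and Defb19, had an X share of 0.121% and Id4 at 59.9 CPM. Both values lay between those of mid to late spermatocyte-like clusters 22 (0.0613% and 137.5 CPM) and 16 (0.315% and 42.7 CPM). Cluster 25 had an X share of 1.26% and Id4 at 21.6 CPM. The leading genes of cluster 19 alone thus do not name its cells. Cluster 6, with 153 cells, 80.4% of them from EGFP-unselected, was led by Dcn, Gsn, Mgp and Igf1, genes of connective tissue cells. The X share was 3.85% in peritubular myoid-like and 3.73% in endothelial-like cells of EGFP-dim.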
